A study of Mus musculus with 8 samples.

How the data were processed

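Chromatin accessibility was measured by ATAC-seq, in which a transposase inserts sequencing adapters into open DNA, in live EpCAM-positive cells sorted from mouse colon tumors. Per the labels' protocols, 10000 organoids of passage 1 (P1) or passage 5 (P5) were placed into the colon wall of C57BL/6N mice, and the tumors were taken 5 weeks later. Nuclei were tagmented with a Nextera enzyme and libraries were made with an Active Motif ATAC-seq kit. There were 4 libraries per group. Each came from 1 mouse, except P5 replicate 4, which was a pool of 2 mice.

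The deposited table holds 1 normalized signal per peak and sample, over 145740 peaks shared by all 8 samples. Of these peaks, 98.72% were 401 bp wide and the widest was 1408 bp. The submitters' processing notes name cutadapt 2.5, Bowtie2 2.3.4.3, SAMtools 1.9, Picard 2.20.7, MACS2 2.2.4 and DiffBind, and the builds mm10 and GRCm38, without giving the role or order of each. Whether read ends were shifted for the cut offset of the transposase, how duplicates were treated and how the peak set was merged are not given in the sources used here. In each sample 100.0% of the deposited values were whole multiples of that sample's smallest value, within a tolerance of 0.01 of a read. The values are therefore read counts divided by 1 factor per sample, and the reads behind them were recovered. How the authors chose the factor is not given in the sources used here. Relative to size factors computed with DESeq2 from the recovered reads, the deposited factors lay between 0.962 and 1.035.

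Recovered reads in peaks ran from 10.9 M to 21.6 M per sample, and the median peak held 17 to 46 reads. Normalized totals were 13.2 to 14.4 M in P1 tumors, 18.6 to 19.6 M in P5 replicates 1 to 3 and 14.9 M in P5 replicate 4. Reads were not counted by unique molecule, so counting error understates the error of a single library. Between 12 and 1463 peaks per sample were listed at 0.

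Chromosomes are coded as whole numbers in the table. Reading the codes in text-sorted order placed 0 peaks more than 1 Mb beyond the last gene of a chromosome and 11.34% of peaks within 1 kb of a gene end, against 29015 peaks and 2.99% in numeric order, so the text-sorted order was used. Genes came from a RefSeq table of the GRCm38.p6 assembly, protein-coding genes only. That table gives no strand. The gene start was therefore approximated by the gene end whose strongest peak within 1 kb had the higher mean over all samples, or by both ends where neither had a peak. Of 21887 coding genes, 10915 had a peak at 1 end, 2853 at both and 7863 at neither, and the other 256 lay on chromosome Y, where the table has no peaks. A peak was assigned to the nearest such start within 50 kb, which gave a gene to 97690 peaks (67.03%). "Promoter" below means within 1 kb of this approximate start, which held for 13995 peaks. Exons and introns were not told apart. Nearest-gene assignment does not show that a peak regulates that gene. Coordinates are as deposited, in mm10/GRCm38, with both ends included.

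The main test was limma 3.58.1 (trend and robust options, R 4.3.3) on log2(value + 1) with passage as the only term, over all 145740 peaks, with Benjamini-Hochberg adjustment and a threshold of 0.05. No peaks were removed. Fold changes are on the log2(value + 1) scale, which understates the change of weak peaks. A second count took peaks past the threshold with at least a 2-fold change. Lists of genes were tested with limma's camera at a preset correlation of 0.01 between peaks, adjusted over 19 lists, with an estimated correlation and limma's fry beside it. Camera compares a list with the other peaks, and fry asks whether the peaks of a list move, on balance, one way, without such a comparison. The design, the lists, the naming rule and the other settings below, except cyclic loess, were fixed before the data were examined. Named peaks were the 10 largest rises and the 10 largest falls among peaks past the threshold whose mean of log2(value + 1) exceeded the median of that mean over all peaks, whose groups did not overlap and whose nearest gene within 50 kb had a name, 1 peak per gene. Further names were, for each list, up to 2 genes per direction with the smallest adjusted p by their best peak, the 5 genes with most peaks past the threshold in each direction (ties by the larger median change), and the promoters of Apc, Kras, Trp53, Smad4 and Epcam. Other genes of a list are named where they help describe it, and these were chosen after their values were seen. List names were matched to the gene table, with 1 name not matched.

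On simulated data for P5 against P1 tumors, with 200 of 145740 peaks changed, the test recovered 19.4% of peaks changed 1.5-fold, 80.6% of those changed 2-fold and 100% of those changed 4-fold, with 3 calls among unchanged peaks. The changed peaks were drawn from those above the median P1 mean, with a dispersion of 0.02 for all peaks. In the data 59.8% of peaks were called, so these rates describe neither weak peaks nor the power of the real comparison. Samples of a group were compared for duplicate libraries by a chi-square of their reads per degree of freedom, which ran from 1.44 to 8.33, so all 8 were counted as separate samples.

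Alternatives were pseudocounts of 0.5 and 5, removal of the 25% of peaks with the lowest mean, centring of each sample on its median, quantile normalization, a replicate block, leaving out each replicate, centring of 10 Mb windows, limma without its trend and robust options, and, on the recovered reads, edgeR 4.0.16 (quasi-likelihood) and DESeq2 1.42.0. Lists were also tested with promoter peaks only and with a 10 kb limit. Cyclic loess was added after seeing the data, because the direction of change followed the mean signal of a peak. Corrections for GC content and the planned comparison of transcription factor motifs need a genome sequence, which was not used here, so motif accessibility was not analysed here. Tables were made with Python 3.11.15, pandas 2.3.3, numpy 2.4.6 and scipy 1.17.1, and figures with matplotlib.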

Results

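Colon tumors grown from P1 and P5 organoids were compared to ask how chromatin accessibility differs after repeated passage through mice, with attention to MAPK- and Wnt-linked regulation. The organoids came from mouse small intestine and carried mutations in Apc, Kras, Tp53 and Smad4 (AKPS), genes of the Wnt, MAPK, p53 and TGF-beta pathways, and P5 organoids had been passaged in mice more often than P1. Accessibility was profiled in sorted EpCAM-positive cells of 4 P1 and 4 P5 tumors, with 1 P5 library pooled from 2 mice. The replicates were recipient mice, and whether a group held separately passaged organoid lines is not given in the sources used here. The tests measure spread between tumors, and without separate lines they cannot tell an effect of passage from a change particular to 1 line. Between 10.9 M and 21.6 M reads per sample fell in 145740 shared peaks, and values are reads divided by the authors' factor for each sample. Across peaks, log2 signal correlated at 0.955 to 0.972 between P1 tumors and at 0.782 to 0.816 between a P1 and a P5 tumor. P5 replicates 1 to 3 correlated at 0.958 to 0.972 with each other, and the pooled P5 replicate 4 at 0.929 to 0.934 with them.

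P5 tumors differed from P1 tumors at 87198 peaks, 59.8% of those tested (limma, adjusted p under 0.05). Accessibility was higher in P5 tumors at 44812 peaks and lower at 42386. The change was at least 2-fold at 49637 peaks, of which 18015 were higher and 31622 lower. The groups did not overlap at 50.6% of peaks, against 2.86% by chance. The direction followed signal strength. Among the 10% of peaks with the strongest signal, 9852 were higher and 146 lower, and among the weakest 10%, 857 were higher and 9315 lower. Promoters were higher at 6307 of 13995 peaks and lower at 2132. After cyclic loess, which removes a trend with signal and was added after seeing the data, 35864 peaks were higher and 37191 lower, and the promoter counts turned to 2102 higher and 5657 lower. Without the 25% of peaks with the lowest mean, 42002 peaks were higher and 24961 lower, and 31607 changed at least 2-fold. Centring each sample on its median moved the median change of all peaks from 0.00 to 0.19 on the log2 scale.

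**Figure D1:**
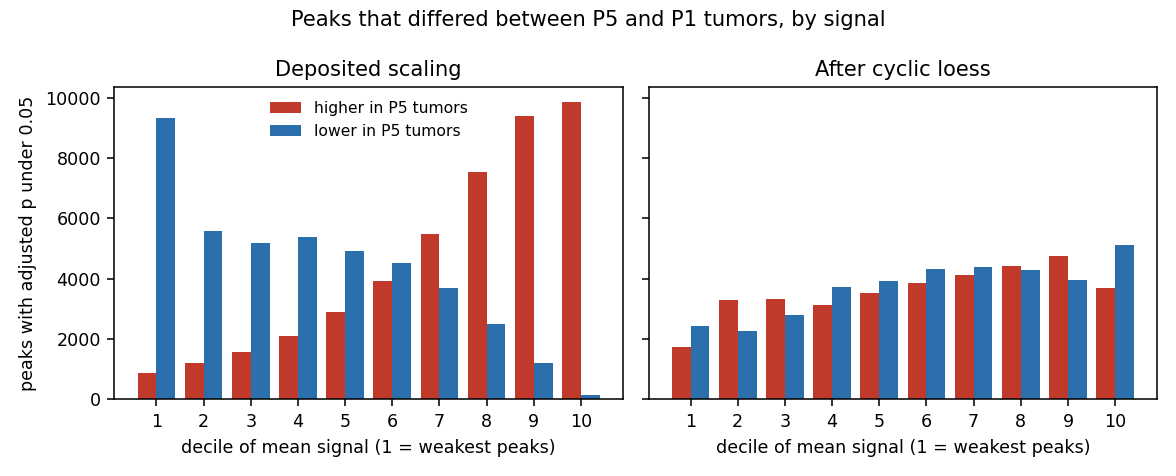
Number of peaks (vertical axis) with adjusted p under 0.05 that were higher (red) or lower (blue) in P5 than in P1 tumors, in 10 classes of mean signal (horizontal axis), with the deposited scaling on the left and after cyclic loess on the right. With the deposited scaling the strongest class held 9852 higher and 146 lower peaks, and after cyclic loess 3700 and 5117.

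The largest losses in P5 tumors lay near Tgfbi, Stk32b and Fzd10, and reached 81.9-fold. A peak 8192 bp from the start of Tgfbi, a matrix protein induced by TGF-beta, had 345 ± 27.7 normalized reads in P1 and 3.58 ± 2.3 in P5 tumors (SD, n = 4 each; chromosome 13, 56601194 to 56601594, outside the gene), a log2 change of -6.36 with SE 0.27 and a limma adjusted p of 2.67e-10. All 15 peaks assigned to Tgfbi were lower. A peak within Pitx2, a homeobox factor, fell from 626 ± 81.7 to 18.9 ± 5.81 reads (chromosome 3, 129213667 to 129214067), and all 12 Pitx2 peaks were lower. Peaks near Stk32b, Fzd10 (a Wnt receptor), Dgki, Gabrp, Fam167a, Astn2, Gpr142 and Scnn1b (a subunit of the epithelial sodium channel) fell, with log2 changes of -6.08, -5.43, -5.33, -5.29, -5.17, -5.12, -4.95 and -4.93. The genes with most lower peaks were Scnn1b (22 of 23), Nkd1 (21 of 27), Isx, an intestinal homeobox factor (20 of 20), Gli2, a Hedgehog pathway factor (19 of 20), and Edn2 (19 of 22).

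The largest gains were smaller in fold and began from low signal in P1 tumors. A peak within Arl15 rose from 6.02 ± 3.31 to 163 ± 13.9 reads (chromosome 13, 113842378 to 113842778), a log2 change of 4.69 with SE 0.30 and a limma adjusted p of 6.45e-09. Peaks near Cobll1, Supt4a, Cfdp1, Fhad1, Eea1, Gpr39, Slc5a7, Syt14 and Tgm1 rose by log2 changes of 4.64, 4.49, 4.41, 4.36, 4.34, 4.29, 4.26, 3.95 and 3.90. The genes with most higher peaks were Wnt7b, a Wnt ligand (27 of 27), Cd44, a hyaluronan receptor (26 of 34), Cd9 (26 of 31), Sdc1 (26 of 31) and Cdh1, E-cadherin (25 of 29). Of these, Wnt7b, Cd9 and Sdc1 lie on chromosomes 15, 6 and 12, which shifted upward as a whole by 0.35, 0.26 and 0.21, as described below. Cd44 and Cdh1 lie on chromosomes 2 and 8, with shifts of -0.004 and 0.06. The best Wnt7b peak, in the gene body, went from 68.7 ± 9.81 to 370 ± 93.7 reads, and the best Cd44 peak, also in the gene body, from 134 ± 3.38 to 364 ± 33.9 reads. P5 replicate 4 had 442 and 303 reads at the Supt4a and Tgm1 peaks, below the 786 to 825 and 522 to 554 reads of the other P5 tumors.

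**Figure D2:**
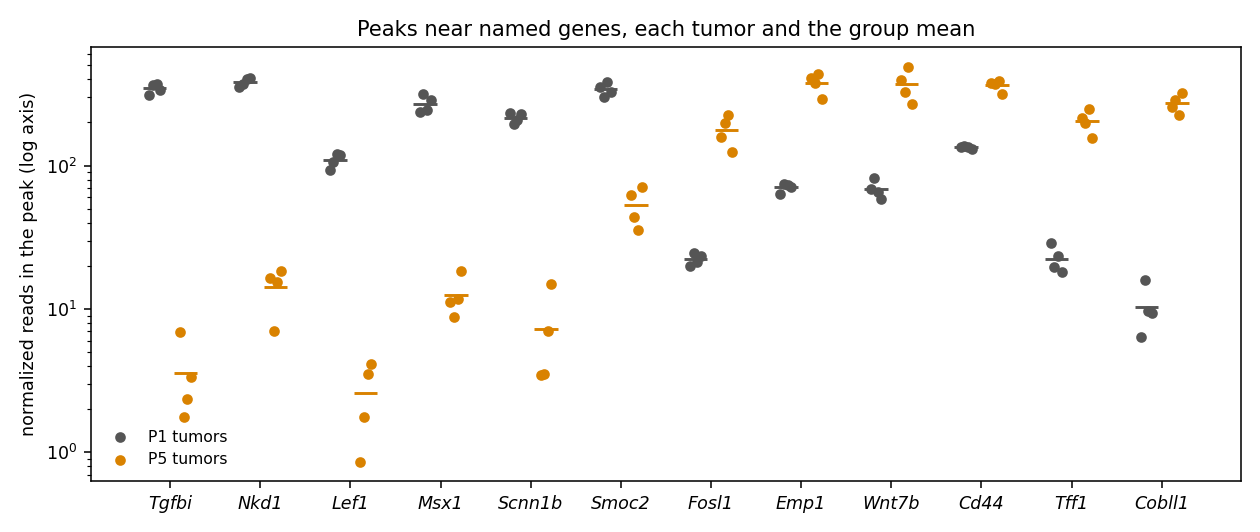
Normalized reads (vertical, log axis) in 12 peaks near named genes for each P1 (gray) and P5 (orange) tumor, with group means as lines. The Tgfbi peak averaged 345 reads in P1 and 3.58 in P5 tumors, and the Cobll1 peak 10.3 and 272 reads.

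Genes of MAPK/ERK output and feedback, which encode the transcription factors, phosphatases and ligands that ERK activity induces, were mostly more accessible in P5 tumors with the deposited scaling. Of 397 peaks assigned to 28 such genes, 210 were higher, 44 lower and 143 did not pass (211 and 46 adjusted over the list alone), with a median log2 change of 0.48. Higher peaks outnumbered lower ones at 21 genes, and the reverse held at 4. After cyclic loess 129 peaks were higher and 71 lower, with 15 and 10 such genes. Epha2 was higher at 24 of 26 peaks, Fos at 17 of 26 (but 8 higher and 3 lower after cyclic loess), Ier3 at 15 of 17 and Dusp5 at 13 of 22. A peak 10641 bp from Fosl1, an AP-1 factor, rose from 22.4 ± 2.08 to 176 ± 43.9 reads (chromosome 19, 5436857 to 5437257), with a log2 change of 2.89, SE 0.19 and a limma adjusted p of 7.76e-09, and a peak within Epha4 rose by a log2 change of 2.10. The members did not all move one way. Dusp6, an ERK phosphatase, was higher at 6 and lower at 6 of 22 peaks, and Etv5 higher at 3 and lower at 6 of 13, with its best lower peak at -2.46. A peak near Areg fell by 2.09, but Areg was higher at 7 and lower at 3 of 16 peaks (3 and 4 after cyclic loess). The list moved up against other peaks (camera adjusted p = 6.4e-05), but adjusted p = 0.90 with an estimated correlation, and after cyclic loess its median was 0.13 with adjusted p = 0.15. Quantile normalization also ended this call (adjusted p = 0.099), and over all alternatives the adjusted p ran from 4.34e-06 to 0.93.

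Wnt/beta-catenin target genes split into members with gains and members with losses. Of 397 peaks at 26 genes, 134 were higher, 125 lower and 138 did not pass (137 and 126 adjusted over the list alone). After cyclic loess 103 were higher and 134 lower. Losses gathered at Nkd1, Lef1, Prox1, Wif1, Dkk3 and Axin2. Nkd1 was lower at 21 of 27 peaks, Dkk3 at 13 of 20, Axin2 at 13 of 26, Prox1 at 12 of 12, Lef1 at 10 of 14 and Wif1 at 6 of 6. The Nkd1 promoter fell from 384 ± 23.7 to 14.3 ± 4.97 reads (chromosome 8, 88521015 to 88521415), with a log2 change of -4.73, SE 0.22 and a limma adjusted p of 5.65e-10, and a peak 4233 bp from Lef1 fell by 5.06. Gains gathered at Cd44, Tcf7l2 (18 of 28 peaks), Ephb3 (13 of 19, but 4 higher and 3 lower after cyclic loess) and Myc (12 of 15). A peak within Tcf7l2, the main Wnt-responsive TCF factor of the gut, rose from 38.9 ± 4.63 to 422 ± 53.5 reads (chromosome 19, 55768877 to 55769277). The list as a whole did not pass camera (adjusted p = 0.96). Its median of 0.12 and mean of -0.21 differed in sign, as did camera (up) and the mean difference of its test statistic (-0.04). Sox9, Lgr5, Rnf43 and Ascl2 are also counted in the stem cell list, and Bambi in the TGF-beta and BMP list.

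**Figure D3:**
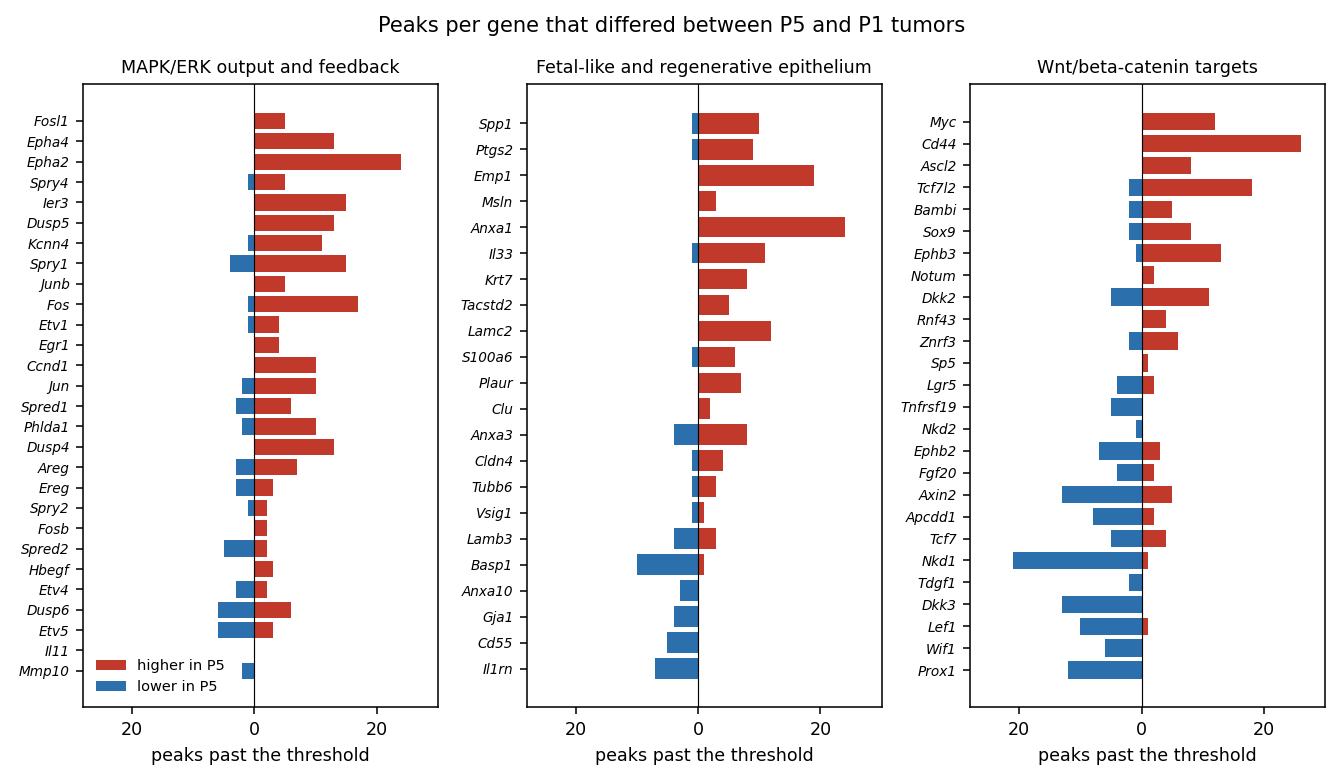
Peaks past the threshold (horizontal axis, higher in P5 tumors to the right in red, lower to the left in blue) for each gene of 3 lists, ordered by the median log2 change of the gene's peaks. Epha2 had 24 higher peaks and no lower ones, Anxa1 24 and 0, and Nkd1 1 higher and 21 lower.

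Genes of fetal-like and regenerative epithelium, a program known from injured intestine, were more accessible in P5 tumors at most members. Of 261 peaks at 22 genes with peaks, 136 were higher, 44 lower and 81 did not pass (140 and 45 adjusted over the list alone, and 114 and 43 after cyclic loess), with a median log2 change of 0.55. Anxa1 was higher at 24 of 30 peaks, Emp1 at 19 of 25, Lamc2 at 12 of 18, Il33 at 11 of 17 and Spp1 at 10 of 11. A peak 27781 bp from Emp1 rose from 70.5 ± 4.79 to 378 ± 62.6 reads (chromosome 6, 135390131 to 135390531), a log2 change of 2.39 with SE 0.14 and a limma adjusted p of 3.14e-09, and a peak near Ptgs2, the inducible prostaglandin synthase, rose by a log2 change of 1.91. At 6 genes lower peaks outnumbered higher ones, among them Basp1 (10 of 21 peaks lower), Il1rn (7 of 8) and Cd55 (5 of 7), with log2 changes of -2.13 at a peak near Il1rn and -2.25 at a peak within Cd55. The list passed camera with the deposited scaling (adjusted p = 9.9e-05) and after cyclic loess (median 0.35, adjusted p = 0.0042), but adjusted p = 0.90 and 0.18 in turn with an estimated correlation. Over all alternatives the adjusted p ran from 4.78e-05 to 0.896.

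Lists of YAP/TEAD targets and of epithelial-mesenchymal transition and invasion did not pass camera, with adjusted p of 0.21 and 0.27. Among YAP/TEAD targets 102 of 254 peaks were higher and 67 lower (103 and 68 adjusted over the list alone, and 74 and 64 after cyclic loess). Myof (14 of 15 peaks) and Ccn2 (14 of 21, but 5 higher and 2 lower after cyclic loess) had mostly higher peaks. Peaks of Asap1 and Crim1 rose by log2 changes of 2.43 and 2.85. Tgfb2 (10 of 12) and Amotl2 (10 of 19) were mostly lower, and Ccn1 was higher at 6 and lower at 6 of 17 peaks, with a best lower peak at -2.13. Among genes of transition and invasion 54 of 148 peaks were higher and 32 lower, the same counts as adjusted over the list alone, and 43 and 29 after cyclic loess. Itgb6, an epithelial integrin (15 of 26 peaks), Snai1 (7 of 13), Prrx1 (4 of 5), Zeb2 (3 of 6) and Lgals1 (3 of 3) had more higher than lower peaks, with the higher ones given here. After cyclic loess Itgb6 had 7 higher and 3 lower peaks. Zeb1 (5 of 7), Vim (4 of 5) and Twist1 (3 of 4) were mostly lower, the Snai2 promoter fell by 3.12, and the Tnc promoter fell by 2.54 although 7 of its 14 peaks were higher. The mean log2 signal of the fibroblast and muscle list was also lower in each P5 tumor (4.70 to 4.99) than in each P1 tumor (5.00 to 5.16). So was the median signal of all peaks.

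Lists of intestinal cell identity changed in both directions and none passed camera. Of 199 peaks at stem cell genes, 70 were higher and 56 lower (71 and 56 adjusted over the list alone, and 61 and 53 after cyclic loess; camera adjusted p = 0.50), and the median of 0.21 and mean of -0.08 differed in sign. Olfm4 was lower at 6 of 6 peaks, Fstl1 at 7 of 7 (but 2 of 7 after cyclic loess) and Smoc2 at 15 of 18. The Smoc2 promoter fell from 343 ± 34.8 to 53 ± 16.2 reads (chromosome 17, 14279291 to 14279691). Cdk6 was higher at 16 of 27 peaks and Ascl2 at 8 of 8 (4 of 8 after cyclic loess), a Sox9 peak rose by a log2 change of 3.46, and Lgr5 was higher at 2 and lower at 4 of 15. Of 135 enterocyte peaks 31 were higher and 50 lower, of 107 goblet and Paneth peaks 27 and 37, and of 108 enteroendocrine and tuft peaks 24 and 31, each the same counts adjusted over the list alone, with camera adjusted p of 0.50, 0.58 and 0.50. After cyclic loess these 3 lists had 28 and 43, 24 and 30, and 29 and 28 higher and lower peaks. Slc5a1, a glucose transporter (10 of 13), Atoh1, the secretory lineage factor (10 of 13), Muc2 (5 of 6), Pax6 (5 of 6) and Dclk1 (3 of 3) were mostly lower, and Fabp2 (8 of 13), Agr2 (8 of 11), Ptgs1 (10 of 13) and Avil (5 of 5) mostly higher. In P5 replicate 4 the mean log2 signal of the goblet and Paneth list was 5.61, against a mean of 5.29 over the other P5 tumors, and that of the enterocyte list 5.38 against 5.11. Genes of regional identity were higher at 38 of 174 peaks and lower at 48 (38 and 46 adjusted over the list alone; adjusted p = 0.36), but at 39 and 37 after cyclic loess, where the median went from -0.39 to 0.02. Gata4, a factor of the proximal intestine, was lower at 7 of 12 peaks and Barx1, a stomach factor, at 6 of 8. The promoter of Tff1, a stomach trefoil peptide, rose from 22.5 ± 4.75 to 204 ± 37.8 reads (chromosome 17, 31164987 to 31165387), and that of Hoxa13, a hindgut factor, rose by a log2 change of 1.28. The promoters of Hoxb13 and Hoxd13 went the other way, with log2 changes of -1.03 and -0.81 (limma adjusted p of 0.0191 and 0.00314).

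TGF-beta and BMP response genes, downstream of the Smad4 pathway, were higher at 101 of 253 peaks and lower at 62 (101 and 63 adjusted over the list alone, but 72 and 73 after cyclic loess; camera adjusted p = 0.50), and the median of 0.12 and mean of -0.11 differed in sign. Besides Tgfbi, Msx1 (5 of 5 peaks) and Msx2 (5 of 7) were lower, and the Msx1 promoter fell by 4.36. Smad7 (17 of 24), Pmepa1 (13 of 18), Tgif1 (12 of 19) and Id2 (12 of 15) were mostly higher, and peaks near Bambi and within Ski rose by log2 changes of 4.10 and 2.24. After cyclic loess Smad7 had 14 higher and 1 lower peaks and Id2 11 and 0, but Pmepa1 only 6 and 2 and Tgif1 7 and 4. The 4 engineered loci together had 10 higher and 7 lower of 37 peaks, also when adjusted over the list alone, and 11 and 9 after cyclic loess (adjusted p = 0.96), with a median of 0.03 and a mean of -0.10. Their promoters had log2 changes of 0.53 (Apc), 1.05 (Kras), 0.40 (Trp53) and 0.66 (Smad4), with limma adjusted p of 0.00786, 0.00176, 0.0201 and 0.0076, and the Epcam promoter 0.57 with 0.017. After cyclic loess, only Kras of these 5 promoters still passed, at 0.45, and Apc (-0.05), Trp53 (-0.15) and Epcam (-0.03) had the opposite sign. Kras also held 8 of the 11 higher peaks of the engineered loci after cyclic loess. It lies on chromosome 6, which shifted by 0.26 as a whole, as described below. At the Kras promoter P5 replicate 4 had 727 reads, within the 607 to 832 of P1 tumors, against 1737 to 1962 in the other P5 tumors. This was not particular to Kras. At the promoters of Apc (459 reads), Smad4 (526) and Epcam (814) replicate 4 also lay within the range of P1 tumors and below the other P5 tumors. At the Trp53 promoter it had 313 reads, just above P1 tumors (237 to 309) and below the other P5 tumors.

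Among the other lists, housekeeping genes, included as a reference, also passed upward. Of 106 peaks 57 were higher and 7 lower, the same adjusted over the list alone, and 34 and 20 after cyclic loess, with a median log2 change of 0.48, equal to that of the MAPK/ERK list (camera adjusted p = 9.9e-05, but adjusted p = 0.90 with an estimated correlation and 0.22 after cyclic loess, with a range of 4.34e-06 to 0.93 over all alternatives). In P5 replicate 4 the mean log2 signal of this list was 6.70, against 7.08 to 7.12 in the other P5 tumors. Ywhaz was higher at 16 of 23 peaks and Actb at 9 of 14 (4 higher and 4 lower after cyclic loess), and Gusb was lower at 4 of 8. Hypoxia and glycolysis genes were higher at 91 of 213 peaks and lower at 38, and cell cycle genes higher at 48 of 110 and lower at 11, with the same counts adjusted over the list alone and camera adjusted p of 0.063 for each. After cyclic loess they had 55 and 43, and 26 and 16, higher and lower peaks, and their medians went from 0.37 to 0.08 and from 0.34 to 0.03. Without P5 replicate 4 both passed (adjusted p = 0.0135 each), and over all alternatives the adjusted p ran from 0.00482 and 0.000344 to 0.93. Slc2a1 was higher at 13 of 26 peaks and lower at 4, but at 3 and 6 after cyclic loess, Ndrg1 higher at 10 of 16 and E2f2 at 8 of 12 (but 3 higher and 1 lower after cyclic loess). Pgk1 is counted in both the hypoxia and the housekeeping lists. Interferon and antigen presentation genes were higher at 30 of 122 peaks and lower at 42, also adjusted over the list alone (adjusted p = 0.52), and at 20 and 48 after cyclic loess (adjusted p = 0.09, with a range of 0.09 to 0.98 over all alternatives). Of genes for antigen presentation by class II, H2-Ab1 was lower at 5 of 5 peaks, H2-Aa at 4 of 4 and their regulator Ciita at 6 of 13, with no higher peaks, and the H2-Ab1 promoter fell by 2.58, while Irf1 was higher at 10 of 21 (8 higher and 8 lower after cyclic loess). The mean log2 signal of the immune cell list was also lower in each P5 tumor (4.63 to 5.08) than in each P1 tumor (5.14 to 5.23). So was the median signal of all peaks. Ptprc was lower at 7 of 9 peaks and Laptm5 at 5 of 5, but at 3 and 2 after cyclic loess. Csf1r was higher at 7 of 12, and at 8 after cyclic loess.

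Markers of cell types that the EpCAM sort should remove had lower mean log2 signal in each P5 tumor than in each P1 tumor, but their lists did not pass camera. The median of all peaks was lower too, at 29.9 to 34.1 normalized reads in P5 and 34.3 to 36.7 in P1 tumors. The lower list means therefore do not show fewer such cells in P5 tumors. For endothelial and glial genes the means were 5.196 to 5.241 in P5 and 5.49 to 5.55 in P1 tumors, and those of the other 2 lists are given above. Immune genes were higher at 16 of 59 peaks and lower at 20, fibroblast and muscle genes at 26 and 33 of 92, and endothelial and glial genes at 50 and 52 of 162, with the same counts adjusted over each list alone and camera adjusted p of 0.84, 0.73 and 0.84. After cyclic loess the counts were 14 and 12, 21 and 22, and 40 and 39. For the immune list (0.02 and -0.33) and the endothelial and glial list (0.03 and -0.30) the median and mean differed in sign. Ptprc (7 of 9 peaks), Pdgfra (7 of 7), Cdh5 (13 of 15), Sox17 (13 of 13) and Emcn (8 of 9) were mostly lower, and Csf1r (7 of 12), Col6a3 (12 of 18), Rgs5 (7 of 8), Flt1 (14 of 14) and Pecam1 (9 of 16) mostly higher. After cyclic loess the lower peaks of the former genes, in turn, were 3, 3, 9, 9 and 5. The higher peaks of the latter were 8, 10, 7, 11 and 6. These lists do not cover EpCAM-positive host epithelium, which the sort would keep. Its share in P1 and P5 tumors was not measured. A difference in that share therefore cannot be told apart from changes in the tumor cells, also at the identity genes above.

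Limma's fry, which asks whether the peaks of a list move on balance one way and does not compare them with other peaks, passed more lists than camera. Fry was run with the deposited scaling only, so the trend with signal was not removed from its results. It passed upward for the fetal-like (adjusted p = 0.00053), MAPK/ERK (0.0045), housekeeping (0.0075), stem cell (0.0075), hypoxia and glycolysis (0.022), YAP/TEAD (0.022), cell cycle (0.025) and transition and invasion (0.046) lists. It passed downward for the endothelial and glial (0.0075), interferon and antigen presentation (0.022), regional identity (0.046) and enteroendocrine and tuft (0.049) lists. It did not pass for the enterocyte (0.30), goblet and Paneth (0.34), engineered (0.46), immune (0.46), fibroblast and muscle (0.50), TGF-beta and BMP (0.50) and Wnt (0.56) lists. For the Wnt and engineered lists its direction was down, where that of camera was up, and for the stem cell and TGF-beta and BMP lists it was up, where the mean log2 change was -0.08 and -0.11.

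**Figure D4:**
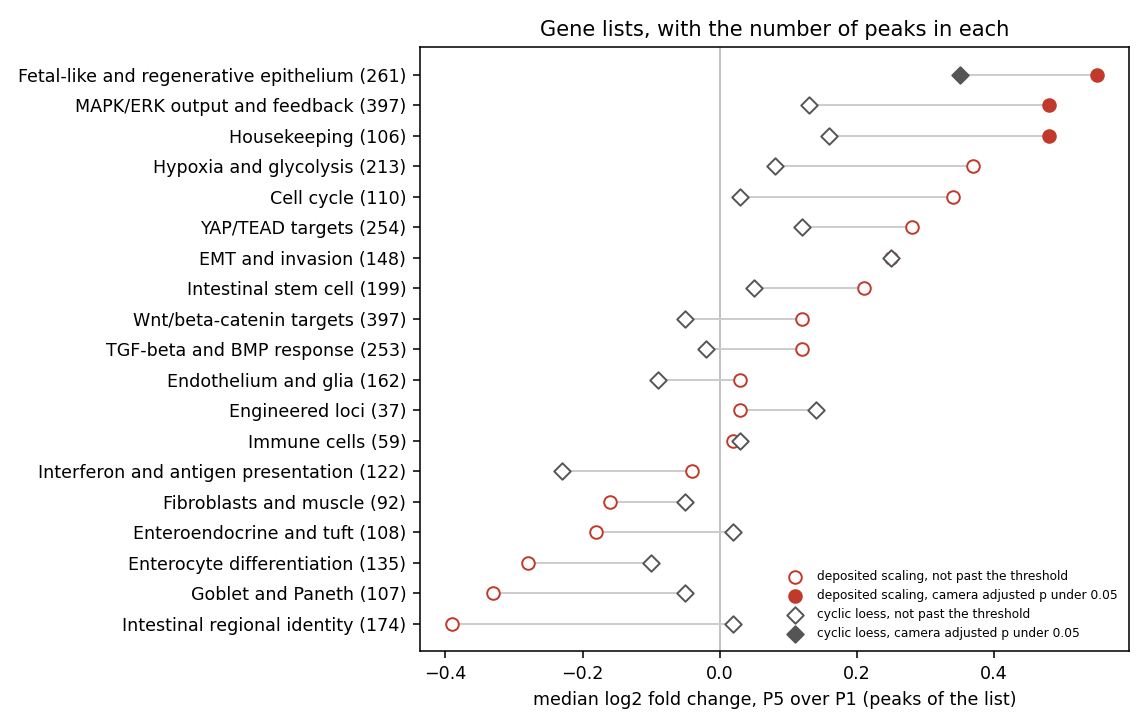
Median log2 change of P5 over P1 (horizontal axis) of the peaks of 19 gene lists, with the number of peaks in parentheses, for the deposited scaling (circles) and after cyclic loess (diamonds), filled where camera's adjusted p was under 0.05. The MAPK/ERK list moved from 0.48 to 0.13 and the fetal-like list from 0.55 to 0.35.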

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

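Dixon's gap test within each group of 4 marked 20 of 258 groups of values, where chance would give about 13. P5 replicate 4 was the outlying library in 11 of the 20. The tests that weigh explanations of P5 replicate 4 below were chosen after the results were seen.

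In P5 replicate 4, the housekeeping list had a mean log2 signal of 6.70 (others 7.08 to 7.12), and reads in single peaks were 442 at Supt4a (others 786 to 825), 303 at Tgm1 (522 to 554), 3.33 at Astn2 (7.03 to 7.76), 116 at Flt1 (146 to 150), 131 at Cd55 (89.6 to 95.0), 27.5 at Il1rn (34.2 to 35.2), 90.7 at Sox9 (185 to 203), 54.1 at Bambi (73.3 to 75.4), 568 at Cd9 (919 to 936) and 71.5 at Edn2 (44.8 to 47.1). P5 replicate 2 had 176 reads at the Ywhaz peak (99.97 to 110 in the others). Among P1 tumors, the immune list in replicate 3 had a mean log2 signal of 5.14 (5.22 to 5.23). Replicate 3 also had 198 reads at Fzd10 (215 to 217), 23.6 at Ski (27.0 to 27.5) and 523 at Edn2 (445 to 447). Replicate 4 had 50.3 at Snai2 (62.5 to 63.8), replicate 2 had 132 at Dclk1 (116 to 117) and 94.4 at Tgfb2 (56.7 to 61.3), and replicate 1 had 157 at H2-Ab1 (118 to 121).

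The pattern of P5 replicate 4, the pool of 2 mice, was weighed against 3 kinds of explanation. Cells that escaped the sort would raise their markers, but relative to the other P5 tumors, with the trend with signal removed, the immune, fibroblast and muscle, and endothelial and glial lists changed by -0.322, -0.188 and -0.02 (log2; SD of the others 0.085, 0.093 and 0.007). P1-like cells in the pool would restore peaks lost in P5 tumors, but at 1372 peaks lower in P5 by 8-fold or more the median shift toward P1 was a fraction of 0.008, while at 2134 peaks higher by 4-fold or more it was 0.318. A trend with signal as the whole cause would leave replicate 4 as close to the others as they are to each other, but with the trend removed its highest correlation with them was 0.357 and their lowest was 0.55. Enterocyte (0.253) and goblet and Paneth (0.294) lists were higher in this library by the same adjusted measure, so differences between the tumors of the pooled mice or EpCAM-positive host epithelium may contribute, neither of which was tested.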

How the results depend on the processing

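Cyclic loess was chosen after seeing the data; the other alternatives were planned. Counts of higher, lower and at least 2-fold changed peaks stayed within 1.5 times under every alternative run, except that without the 25% of weakest peaks, where fewer peaks are tested, 24961 were lower and 31607 changed 2-fold. Leaving out 1 replicate gave 39325 to 51963 higher, 37105 to 48292 lower and 46906 to 55338 changed 2-fold, the highest of each without P5 replicate 4. On recovered reads edgeR called 39493 higher and 45730 lower, and DESeq2 40411 and 40021. Median centring gave 53965 higher and 35338 lower, 60.4% higher against 51.4%. The replicate numbers did not pair the samples (correlations of deviations 0.003, 0.061, 0.016 and 0.196), and the replicate block gave 45463 higher and 43892 lower. The MAPK/ERK call ended with quantile normalization (adjusted p = 0.099), cyclic loess (0.147) and an estimated correlation (0.896), and leaving out 1 replicate kept it. The housekeeping call ended under the same 3 (0.129, 0.217 and 0.896) and the fetal-like call only with an estimated correlation (0.896). For cyclic loess the construction removes the trend with signal. For the others the cause was not tested, but quantile normalization gives all samples the same distribution. Its list medians (0.18 for MAPK/ERK, 0.20 for housekeeping) were close to those of cyclic loess (0.13 and 0.16), so both settings are not independent of each other. The Wnt list, never past the threshold, turned downward without the weakest 25% (0.979), with quantile normalization (0.858), cyclic loess (0.792), promoters only (0.887) and a 10 kb limit (0.792), and in 2 of the 8 fits that left out 1 replicate (0.841 to 0.981 over all 8). Other lists that never passed changed direction without the weakest 25% (endothelium and glia 0.938, engineered loci 0.938, fibroblasts and muscle 0.979, immune 0.938), with quantile normalization (enteroendocrine and tuft 0.989, immune 0.989, TGF-beta and BMP 0.888), with 10 Mb windows centred (engineered loci 0.748), with cyclic loess (enteroendocrine and tuft 0.982, fibroblasts and muscle 0.982, immune 0.983, regional identity 0.982, TGF-beta and BMP 0.863), with promoters only (immune 0.65, interferon 0.976, regional identity 0.887) and with a 10 kb limit (endothelium and glia 0.816, immune 0.792, regional identity 0.926), and, of the 8 fits that left out 1 replicate, in 2 for engineered loci (0.843 to 0.993 over all 8) and in 1 for immune (0.621 to 0.981 over all 8). The cause of these turns was not tested. Calls appeared for cell cycle (0.0135 without P5 replicate 4, 0.0397 with promoters only, 0.000344 with 10 kb), hypoxia (0.0135, 0.0245 and 0.00482, and 0.0492 with the block) and YAP/TEAD (0.0393 with 10 kb). Of 107 named peaks over 19 settings, 2008 comparisons kept direction and side of the threshold, 17 lost the call and 5 turned: the promoters of Apc (-0.025 with quantile normalization, -0.046 with cyclic loess), Trp53 (-0.152 and -0.145) and Epcam (-0.029 with cyclic loess). Apart from the promoters of Apc, Kras, Trp53, Smad4 and Epcam, named peaks were chosen for strong results in these data, which favors such stability. Over all 87198 calls, 56336 kept direction and call after cyclic loess. GC corrections, alone and with the block, and all motif comparisons were not run. Depth limits weak peaks most: the median peak held 17 reads in P5 replicate 2.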

Other observations

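Gene families were compared, and the explanations below tested, after the results were seen, except that the test of gene density was written before it was run. Families were genes with a shared stem of their symbols. Of 215 families with at least 6 genes and 60 peaks, 23 passed camera over all families and 11 of these also after cyclic loess in the same direction, but 0 with an estimated correlation. Keratin genes, which encode the intermediate filaments of epithelia, stood first, with 175 of 262 peaks higher in P5 tumors and 19 lower (median log2 change 0.77, adjusted p = 4.8e-10, and 0.56 with an estimated correlation). Krt80 was higher at 16 of 19 peaks, Krt18 at 16 of 17, Krt78 at 14 of 15, and Krt14, Krt5 and Krt79, of stratified or skin-type epithelium, at 8 of 8, 6 of 6 and 8 of 8, while Krt75 was lower at 6 of 9. On chromosome 11, 68 of 116 keratin peaks were higher (median 0.52, and 0.30 after cyclic loess), and on chromosome 15, 107 of 146 (0.93, and 0.67 after cyclic loess), beside shifts of the whole chromosomes, described below, of -0.04 and 0.35. Annexin genes were higher at 96 of 181 peaks (adjusted p = 6.3e-05, and 0.56 with an estimated correlation), and genes of colony-stimulating factors and their receptors at 38 of 62 (adjusted p = 6.3e-05, and 0.56), with Csf2 higher at 18 of 18.

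Families with losses included the Adamts matrix proteases, lower at 79 of 130 peaks (median -0.95, adjusted p = 1.7e-06, and 0.20 with an estimated correlation), fibroblast growth factors, lower at 44 of 79 (-0.85, 0.0015, and 0.56), and mucins, lower at 49 of 94 (-0.72, 0.0024, and 0.56). After cyclic loess their medians were -0.58, -0.43 and -0.54. Chst genes were lower at 44 of 99 peaks (-0.61, 0.021, and 0.56) and also passed camera after cyclic loess (adjusted p = 0.018). Kcnj (camera adjusted p = 0.0024) and Pla genes (0.028) passed downward with the deposited scaling only. Adamts16 was lower at 16 of 16 peaks, Adamts18 at 10 of 11, Fgf9 at 10 of 10 and Muc13 at 17 of 20, while Adamts10 was higher at 4 of 4, Fgf7 at 3 of 6 and Muc5b at 4 of 9. The keratin, annexin, colony-stimulating factor, Adamts, fibroblast growth factor and mucin families are among the 11 that passed in the same direction after cyclic loess. That choice largely set the sign of their medians under cyclic loess, so the sign there is no further support. The medians of these 6 families kept their sign under median centring, quantile normalization, edgeR and DESeq2, which is no further support either. Median centring, edgeR and DESeq2 put the median change of all peaks at 0.19, -0.10 and -0.04, too small a move to turn these medians. Quantile normalization gave medians close to those of cyclic loess (keratins 0.60 and 0.52, mucins -0.42 and -0.54).

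The link between direction and signal strength was weighed as a hypothesis about library signal-to-noise. As the cause of all calls it is argued against, since 56336 of 87198 peaks were still called in the same direction after cyclic loess. For the MAPK/ERK and housekeeping lists it stays open: their medians of 0.48 and 0.48 became 0.13 and 0.16 and the calls ended (adjusted p = 0.15 and 0.22). The fetal-like list went from 0.55 to 0.35 and still passed (0.0042), which argues against the trend as its whole cause at the preset correlation, but adjusted p = 0.18 after cyclic loess with an estimated correlation. A global biological gain at strong elements in P5 tumors cannot be separated from library quality by these values and stays open.

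The results were also computed for all 35 ways to divide the 8 samples into groups of 4. For the count of calls and the 2-fold count, 1 of 35 splits, the real one, gave as many (87198 and 49637, against 0 and 0 at most in the others), which argues against random differences between samples. The fetal-like p was also smallest in the real split alone (1 of 35; 1.5e-05 against 7.6e-05). For MAPK/ERK, 3 of 35 splits gave a p as small (3.4e-06, smallest other 4.6e-08), and for housekeeping 5 of 35 (1.6e-05, smallest other 2.6e-08), so the splits do not exclude random differences for the camera p of these 2 lists. Each of these other splits exchanged P5 replicate 4 with 1 P1 tumor and had 0 called peaks, so it kept P5 replicates 1 to 3 apart from 3 P1 tumors. The mean log2 signal of both lists separated the groups, with 6.33 to 6.42 in P1 and 6.57 to 6.81 in P5 tumors for MAPK/ERK, and 6.54 to 6.59 and 6.70 to 7.12 for housekeeping. Such means do not compare a list with other peaks. In the strongest of the 10 signal classes 67.6% of all peaks were higher in P5 tumors, so the separation does not bear on the camera p. The Wnt list had no call for splits to test (32 of 35; 0.91, smallest other 0.043).

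Whole chromosomes shifted between P5 and P1 tumors. With the trend with signal removed, the difference of median log2 signal was 0.38 on chromosome 19, 0.35 on 15, 0.26 on 6 and 0.21 on 12, and -0.35 on 14, -0.27 on 13 and -0.26 on 10, the 7 chromosomes with a shift of at least 0.2. Each had an exact two-sided permutation p of 0.0286, the smallest that 4 against 4 allow (adjusted 0.0357 over 20 chromosomes), which 16 of the 20 chromosomes reached, some with shifts under 0.1, as chromosomes 4 (-0.07) and 8 (0.06). The 7 had a sign shared by all 4 P5 against all 4 P1 tumors, and SDs within a group of 0.0080 to 0.0433, and each kept its sign under every alternative run except centring of 10 Mb windows, which removes it by construction. Much of this was fixed in advance. Groups that separate fully can hardly turn when 1 sample is left out, and median centring cancels when the trend is removed. Named gains on these chromosomes include Wnt7b (15), Tcf7l2 and Fosl1 (19), Emp1 and Cd9 (6) and Sdc1 (12). Against their chromosome, Arl15 (13) and Tgm1 (14) rose and Dgki (6) fell. With 10 Mb windows centred, 104 of 107 named peaks kept direction and call and 3 lost the call.

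Differences in chromosome copy number between the organoid passages may account for the shifts, as would any other cause that acts on whole chromosomes. Over all 20 chromosomes, 72.6% of 270 windows of 10 Mb had the sign of the other windows of their chromosome, against 65.6% at most when windows were permuted (permutation p = 0.0001, the smallest the permutations can give), and a full gain of 1 copy over 2 would give 0.58. Removal of gene density, a stand-in for GC content, left the share of the variance between windows that lay between chromosomes at 50.3% (Spearman's rho -0.01 with the shift), so it moved nothing and decides nothing about GC content. GC content itself and DNA copy number were not measured here, and both stay open, as does which passage departs from the normal karyotype.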
